A study of Mus musculus with 8 samples.

How the data were processed

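RNA sequencing measured poly(A)-selected RNA from bone-marrow-derived macrophages, which are macrophages grown from mouse bone marrow cells. The cells came from wild-type mice or from Sept2C111A mice, and every culture had received TNF-α at 30 ng/ml for 24 h. The 8 libraries form 2 groups of 4, taken from the sample labels. Sept2 encodes septin 2, a GTP-binding cytoskeletal protein, and the allele name gives a cysteine-to-alanine change at residue 111 of that protein.

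The deposited values are expected counts per gene symbol, 1 column per library and 17364 genes. An expected count is the number of reads that a model assigns to a gene after sharing out reads that match several genes, so it need not be whole. The submitters' processing notes name Bowtie2, RSEM 1.3.1, DESeq2 1.4.5 and the mouse build mm10, without saying what each was used for. Enrichment of mRNA on oligo(dT) beads is recorded per the labels' protocols. The annotation, the strandedness of the libraries and any filter on genes are not given in the sources used here. Without strand, reads of overlapping antisense genes cannot be told apart, and members of near-identical gene families share reads that the model splits between them.

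The expected counts were rounded to whole numbers. Totals ran from 19543958 in Sept2C111A library 2 to 21288493 in Sept2C111A library 3, and 14857 to 15359 genes had a count above 0. A gene with no read in a library lies below about 0.14 to 0.15 CPM (a gene's reads scaled to a common library total), the level of 3 counts, and this limit covers counting error only. Genes with low counts were removed with filterByExpr at its minimum count of 10, which left 12462 tested genes. Normalization was by trimmed mean of M values (TMM), and CPM values are on the normalized library sizes.

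The comparison of Sept2C111A with wild type was fitted with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with the group as the only term and Benjamini-Hochberg adjustment over the tested genes. A gene was called at an adjusted p under 0.05. The SE of a log2 fold change is the fold change divided by the square root of its F statistic. Gene lists were tested on log2 CPM with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 42 lists with at least 3 tested members. Camera was run again with the correlation estimated from the data, and fry tested whether the genes of a list move on balance 1 way. Of the 892 gene entries in 45 lists, 847 were found among the gene symbols of the files, 28 of them through an older symbol; the others, mitochondrially encoded transcripts among them, were not analysed here.

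Gene symbols were matched to the RefSeq table of the GRCm38 assembly, which is the mm10 build, for 17292 of 17364 symbols, and coordinates come from it. Transcript length and GC content were taken from GENCODE transcripts of the same assembly and covered 98.2% of the tested genes.

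The design, the lists, the rule for naming genes and most of the alternatives were fixed before the data were examined. The rule names Sept2 first. It then takes, among called genes with a mean of at least 2 CPM and no overlap between the groups, the 10 with the largest rise and the 10 with the largest fall, leaving out unnamed gene models. From each list it takes up to 3 called members with the smallest adjusted p, or the most abundant member where none was called. Genes named outside this rule are said to have been chosen after their values were seen.

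The scripts were tested on simulated counts for this comparison, drawn for the genes left by the filter with the real means and library sizes and a biological coefficient of variation of 0.1, of which 12371 were tested. With a true log2 change of 1, 100% of 100 changed genes were called in the right direction, and with a change of 0.5, 81% of 100. There were 10 false calls, and camera called the list that had been changed and 0 others. Genes were drawn independently and with the same coefficient in both groups, where wild-type and Sept2C111A libraries had 0.0604 and 0.138. The simulation therefore does not test list calls among correlated genes, or false calls under unequal spread.

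Pairs of libraries were compared over genes with at least 200 reads in total, and the mean chi-square per gene was at least 3.87 in every pair, where sampling noise alone gives 1. No library was therefore a copy of another. Alternatives covered normalization, filters, each library left out, the most abundant genes, a replicate block, DESeq2 1.42.0, limma voom with and without sample weights, a surrogate variable from sva 3.50.0, thresholds, and other list tests. Alternatives added after the data were seen left out 2 Sept2C111A libraries together, removed trends on length and GC content with mgcv 1.9.3, or took the stromal marker score as a covariate.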

Results

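The series compared gene expression in TNF-treated bone-marrow-derived macrophages of wild-type and Sept2C111A mice, 4 libraries each. Its title places the question in macrophage inflammation and migration and in S-nitrosylated septin 2, nitric oxide being able to modify the thiol of a cysteine. Every library came from cells given TNF-α at 30 ng/ml for 24 h, so the values describe the genotypes in the treated state only. Total expected counts ran from 19543958 to 21288493 per library, a narrow range. The labels do not say that replicates came from separate mice or cultures, and p-values then measure only the spread between these samples, which may be technical.

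The libraries of the 2 genotypes lay apart on the first principal component of log2 CPM, which held 45.1% of the variance. Wild-type libraries lay between -19.4 and -11.2 and Sept2C111A libraries between -1.97 and 36.6. Sept2C111A libraries 2 and 3, at 28.2 and 36.6, stood apart from libraries 1 and 4, at 0.87 and -1.97, on this component. On the second component, Sept2C111A library 4 lay lowest, at -27.5, and library 3 highest, at 15.7. By mean chi-square per gene, Sept2C111A libraries 3 and 4 were the furthest apart of that genotype, at 63.3. Library 1 was about as near to library 2 as to library 4, at 14.2 and 14.1. The biological coefficient of variation was 0.0604 among wild-type and 0.138 among Sept2C111A libraries.

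**Figure D1:**
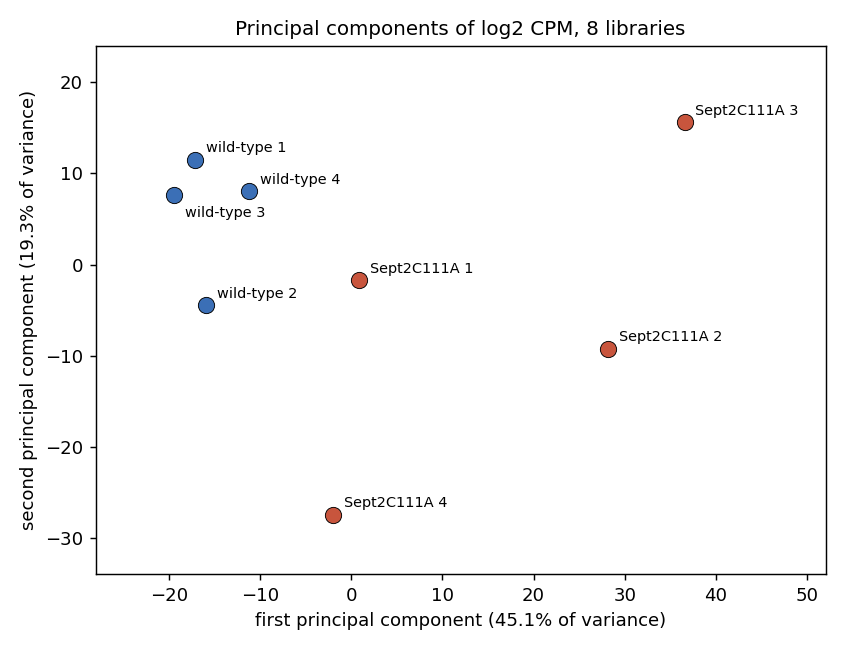
Scores of the 8 libraries on the first (45.1% of variance) and second (19.3%) principal components of log2 CPM, in arbitrary units, blue for wild-type and red for Sept2C111A. The 4 wild-type libraries lie at -11.2 or below on the first component, and Sept2C111A libraries 2 and 3 lie at 28.2 and 36.6.

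Sept2 itself, listed as Septin2, was measured at 226 ± 7.43 CPM in wild-type and 188 ± 18.7 CPM in Sept2C111A libraries (mean ± SD over 4 libraries each, as in all CPM values given with ±). The gene lies on chromosome 1 at 93478981 to 93509733 (mm10). The log2 fold change was -0.27 (SE 0.076), with an adjusted p of 0.063 in edgeR, which did not pass the threshold. All 4 Sept2C111A libraries lay below all 4 wild-type libraries, for which an exact two-sided permutation test of log2 CPM gave p = 0.0286, the smallest that 4 against 4 allows. Gene counts cannot show the base change, so the edited codon was not checked in the libraries. Without Sept2C111A library 3 the log2 fold change was -0.31 and passed, at an adjusted p of 0.029. Over all alternatives the adjusted p ran from 0.00059 to 0.17 and the fold change stayed negative. None of the tested genes among the 10 neighbours on either side of Sept2 was called in edgeR, and Bok came nearest, at a log2 fold change of -0.56 and an adjusted p of 0.058. Among the 9 septins tested, 2 fell and 7 did not pass. Septin11 fell from 133 ± 3.74 to 82.6 ± 11.6 CPM and Septin5 from 26.2 ± 3.85 to 17.7 ± 3.25 CPM. The call of Septin5 was lost on leaving out wild-type library 1, 3 or 4 or Sept2C111A library 2 or 3 (adjusted p 0.062 to 0.13). Adjusted over the list alone, 1 septin rose and 3 fell. Camera did not call the list as a whole (adjusted p = 0.32, and 0.46 with an estimated correlation), while fry called it lower (adjusted p = 0.021).

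Several interferon-regulated genes, major histocompatibility complex class I genes and activating Fc receptor genes had more RNA in Sept2C111A libraries, and several cholesterol synthesis, chemokine and cytokine genes had less. The lists that hold these genes were called by camera at its preset correlation, and all 6 calls were lost, at adjusted p = 0.20 to 0.46 with an estimated correlation. Each library measures a whole culture, in which the stromal marker gene Col1a1 had a mean of 2056 CPM in wild-type and 1545 CPM in Sept2C111A libraries. The counts therefore do not show which cells differed. Of 12462 genes tested, 805 were called, 428 higher and 377 lower in Sept2C111A, and 3092 had an unadjusted p under 0.05. The change was at least 2-fold for 61 of the higher and 35 of the lower genes. The groups did not overlap for 787 of the called genes and for 16.9% of all tested genes, against 2.86% by chance. The median log2 fold change of all tested genes was 0.01. Among the 10 largest rises were Slfn1, a schlafen family gene (5.26 ± 1.64 to 31.1 ± 8.89 CPM), Ly6a, a surface protein gene (10.5 ± 1.39 to 55.5 ± 14.0 CPM), and Ly6e, another (356 ± 69.9 to 1308 ± 411 CPM). Irf7, Ms4a4c, Ifi44, Ifi27l2a, Slfn4, Apol9b and Ifi213 completed the 10, with log2 fold changes of 2.29, 2.23, 2.03, 1.98, 1.92, 1.92 and 1.85. Several of these genes have close copies (Slfn, Ly6, Ms4a4, Apol9, Ifi27l2 and Ifi200 families) whose reads the counting model had to share out, so their separate values are uncertain. The largest falls were in Il4i1, an amino acid oxidase (log2 fold change -1.67, SE 0.19), Tarm1, an activating receptor of myeloid cells (10.6 ± 0.759 to 3.59 ± 0.696 CPM), and Tmem200b. Then came Idi1, Il12b, Marco, Cxcl3, Cxcl1, Socs3 and Tubb2b, with log2 fold changes of -1.34, -1.33, -1.31, -1.30, -1.26, -1.17 and -1.16. All 20 were called with an adjusted p of 0.018 or less. The call of Idi1 was lost without wild-type library 2, 3 or 4 or Sept2C111A library 2 (adjusted p 0.051 to 0.065).

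Of 42 gene lists tested, camera called 19 at its preset correlation, 7 higher and 12 lower. With an estimated correlation it called 0, where 6 had an unadjusted p under 0.05. Fry called 21, of which 15 were among the 19 with the same direction. Another split of the 8 libraries into 4 and 4 gave 20 lists by camera at its preset correlation. The number of called genes depended on single libraries. It was 281, 475, 266 and 376 without wild-type library 1, 2, 3 or 4. Without Sept2C111A library 2 it was 361, and without Sept2C111A library 4 it was 2077. Without Sept2C111A libraries 2 and 3 together it was 492, of which 416 were among the 805 with the same sign.

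**Figure D2:**
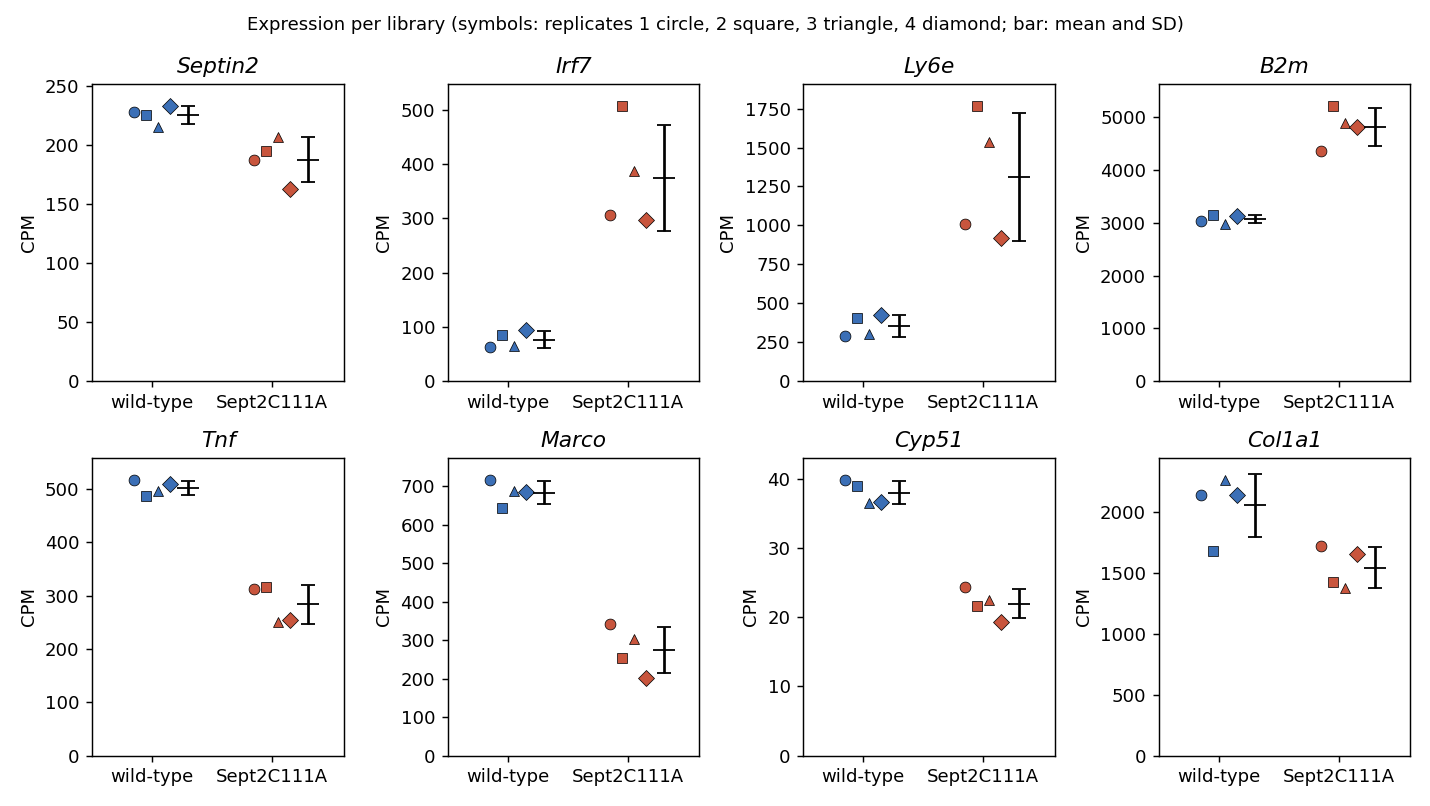
CPM per library for 8 genes, with points for replicates 1 to 4, wild-type in blue and Sept2C111A in red, and a bar for the mean and SD (n = 4). Irf7, Ly6e and B2m lie higher in every Sept2C111A library, Septin2, Tnf, Marco and Cyp51 lower in every one, and the groups overlap for Col1a1.

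The list of interferon-stimulated genes was called higher by camera at the preset correlation (median log2 fold change 0.44, adjusted p = 7.87e-07). The call was lost, at adjusted p = 0.46 with an estimated correlation, and fry gave an adjusted p of 0.051. Of 35 tested members, 17 rose, 2 fell and 16 did not pass, 9 had a negative log2 fold change, and adjusted over the list alone 20 rose and 5 fell. Irf7, a transcription factor of the interferon response, rose from 76.5 ± 15.2 to 374 ± 97.4 CPM (log2 fold change 2.29, SE 0.19). Oas3, a sensor of double-stranded RNA, rose from 43.6 ± 5.51 to 126 ± 22.2 CPM, and Ifi44 from 13.6 ± 4.04 to 55.4 ± 12.6 CPM. The 2 that fell were Gbp5, a guanylate-binding protein gene (184 ± 21.4 to 109 ± 27.2 CPM), and Irf1, a transcription factor gene (350 ± 16.8 to 275 ± 31.9 CPM). These and the following values were chosen after they were seen. Ifit1 measured 162 ± 25.3 CPM in wild-type and 147 ± 34.7 CPM in Sept2C111A libraries, and Isg15 62.9 ± 11.9 and 91.3 ± 23.7 CPM, neither of them called. The rises numbered 10 without wild-type library 1 or 3 and 11 without Sept2C111A library 2. Without Sept2C111A libraries 2 and 3 they numbered 11, with 3 falls. The list's mean log2 CPM was 6.179 and 6.198 in wild-type libraries 1 and 3, and 6.485 and 6.526 in wild-type libraries 2 and 4. In the Sept2C111A libraries it ran from 6.64, in library 4, to 7.13, in library 2. The list therefore also varied among libraries of the same genotype.

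All 19 tested genes of class I antigen presentation had a positive log2 fold change, and 11 of them were called. The light chain gene B2m rose from 3074 ± 80.4 to 4817 ± 355 CPM. H2-T23 rose from 157 ± 7.83 to 331 ± 55.3 CPM and H2-Q7 from 24.1 ± 3.77 to 71.2 ± 9.31 CPM. Class I heavy chain genes are close copies of each other, so the split of reads among them is uncertain; B2m has no such copy. There were 14 rises and 0 falls adjusted over the list alone. The median log2 fold change was 0.53 (camera adjusted p = 5.64e-11, and adjusted p = 0.35 with an estimated correlation), and 9 members rose without Sept2C111A libraries 2 and 3. Of 8 class II genes, only H2-DMb1 was called, a rise from 28.6 ± 1.76 to 38.6 ± 5.32 CPM, lost without any single wild-type library or Sept2C111A library 2 (adjusted p 0.051 to 0.11). The class II list was not called (camera adjusted p = 0.85, and 0.94 with an estimated correlation), and its median of -0.19 and mean of 0.0037 differed in sign. Among 16 complement and Fc receptor genes, 5 rose and 2 fell, and adjusted over the list alone 9 rose and 4 fell. The activating Fc receptor genes Fcgr1, Fcgr3 and Fcgr4 rose, with log2 fold changes of 1.18, 0.64 and 1.00 (SE 0.14, 0.087 and 0.13). C3ar1 and C4b also rose, and C5ar1 and the inhibitory receptor gene Fcgr2b fell, the call of C5ar1 being lost without any single wild-type library or Sept2C111A library 2 (adjusted p 0.061 to 0.098). C3ar1, C4b and Fcgr2b were named after their values were seen. This list was called higher (camera adjusted p = 0.0044, and adjusted p = 0.44 with an estimated correlation), and without Sept2C111A libraries 2 and 3 it was not (adjusted p = 0.061, 3 members higher and 2 lower). Leaving out any single wild-type library or Sept2C111A library 2 left 3 rises in it, those of Fcgr1, Fcgr3 and Fcgr4, and ended the calls of C3ar1 and C4b. Leaving out Sept2C111A library 4 gave 11 rises and 4 falls.

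Lists of inflammatory genes were called lower by camera at the preset correlation, the cytokine, chemokine, NF-κB and classical activation lists with adjusted p = 0.049, 3.96e-06, 3.96e-06 and 0.00032. All 4 calls were lost, at adjusted p = 0.45, 0.22, 0.34 and 0.20 with an estimated correlation, and the list of stromal markers had a median log2 fold change of -0.41 in the same libraries. Among 15 cytokine genes, 6 fell and 9 did not pass. Tnf fell from 502 ± 13.3 to 284 ± 36.1 CPM (log2 fold change -0.82, SE 0.087), Tnfsf9 from 44.4 ± 1.46 to 24.3 ± 2.68 CPM, and Il12b, the interleukin 12 and 23 subunit gene, from 3.82 ± 0.896 to 1.52 ± 0.301 CPM. Il1b, chosen after its values were seen, measured 45.7 ± 5.60 and 58.3 ± 17.3 CPM and was not called. Of 22 chemokine genes, 9 fell, 1 rose and 12 did not pass. The neutrophil chemoattractant genes Cxcl1 and Cxcl2 fell from 8.84 ± 1.07 to 3.67 ± 0.994 CPM and from 198 ± 9.51 to 129 ± 12.5 CPM, and Ccl3 fell from 172 ± 6.24 to 116 ± 11.4 CPM. Ccl6, the member that rose, went from 468 ± 14.6 to 672 ± 68.8 CPM and was chosen after its values were seen. In the list of NF-κB and TNF signalling, 8 of 29 genes fell and 0 rose, among them the inhibitor gene Nfkbia (605 ± 18.0 to 465 ± 21.6 CPM), Ripk2 (60.3 ± 2.98 to 42.0 ± 4.68 CPM) and Tnfaip2 (1941 ± 84.9 to 1400 ± 140 CPM). Of 15 markers of classical macrophage activation, 7 fell and 1 rose. Marco, a scavenger receptor gene, fell from 684 ± 30.1 to 275 ± 60.7 CPM, and Socs3, a feedback inhibitor of cytokine signalling, from 90.7 ± 4.35 to 40.3 ± 9.34 CPM. The riser was Cd86, chosen after its values were seen, with a log2 fold change of 0.46.

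Tnf and Il12b belong to both the cytokine and the classical activation lists. The call of the cytokine list was lost without wild-type library 3 or 4 or Sept2C111A library 1 or 4 (adjusted p 0.051 to 0.15), with the replicate block (0.091) and with no filter on low counts (0.080). Adjusted over the list alone, 3 cytokine genes rose and 6 fell, 2 chemokine genes rose and 14 fell, 0 NF-κB genes rose and 13 fell, and 1 classical activation marker rose and 8 fell. The falls numbered 6, 9, 11 and 6 without Sept2C111A libraries 2 and 3. Among chemokines, 4 fell without wild-type library 3 and 5 without wild-type library 4. Among NF-κB genes, 5 fell without wild-type library 1 and 4 without wild-type library 2, 3 or 4. The rise of Cd86 was lost without wild-type library 1, 3 or 4 or Sept2C111A library 2.

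Cholesterol biosynthesis had the largest share of called genes among the 19 lists that camera called. Of 23 tested, 16 fell, 0 rose and 7 did not pass, and 18 fell when adjusted over the list alone. Cyp51, a sterol demethylase, fell from 38.0 ± 1.68 to 21.9 ± 2.09 CPM, Sqle, the squalene epoxidase, from 25.9 ± 1.32 to 12.3 ± 2.28 CPM, and Hmgcs1, the synthase at the head of the pathway, from 57.5 ± 3.44 to 38.2 ± 2.05 CPM. The list's median log2 fold change was -0.58 (camera adjusted p = 3.15e-11, and adjusted p = 0.20 with an estimated correlation). There were 15 falls without Sept2C111A libraries 2 and 3. Among 16 genes of lipid efflux and liver X receptor targets, Apoe and Pltp rose and Fasn and Scd2 fell, Pltp being named after its values were seen. Apoe, the gene with the highest mean CPM over the 8 libraries, went from 19749 ± 965 to 30443 ± 6925 CPM, and its call was lost without any single wild-type library or Sept2C111A library 2 (adjusted p 0.072 to 0.090). The lipid synthesis genes Fasn and Scd2 had log2 fold changes of -0.48 and -0.68, and their calls were lost without wild-type library 1, 3 or 4 or Sept2C111A library 2, and for Fasn also wild-type library 2 (adjusted p 0.072 to 0.10). No gene of that list was called without wild-type library 1, 3 or 4 or Sept2C111A library 2, only 1 fall without wild-type library 2, 4 rose and 3 fell without Sept2C111A library 1, and 5 rose and 3 fell without Sept2C111A library 4. In the list, 5 rose and 3 fell adjusted over the list alone, and it was not called (camera adjusted p = 0.35, and 0.46 with an estimated correlation).

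**Figure D3:**
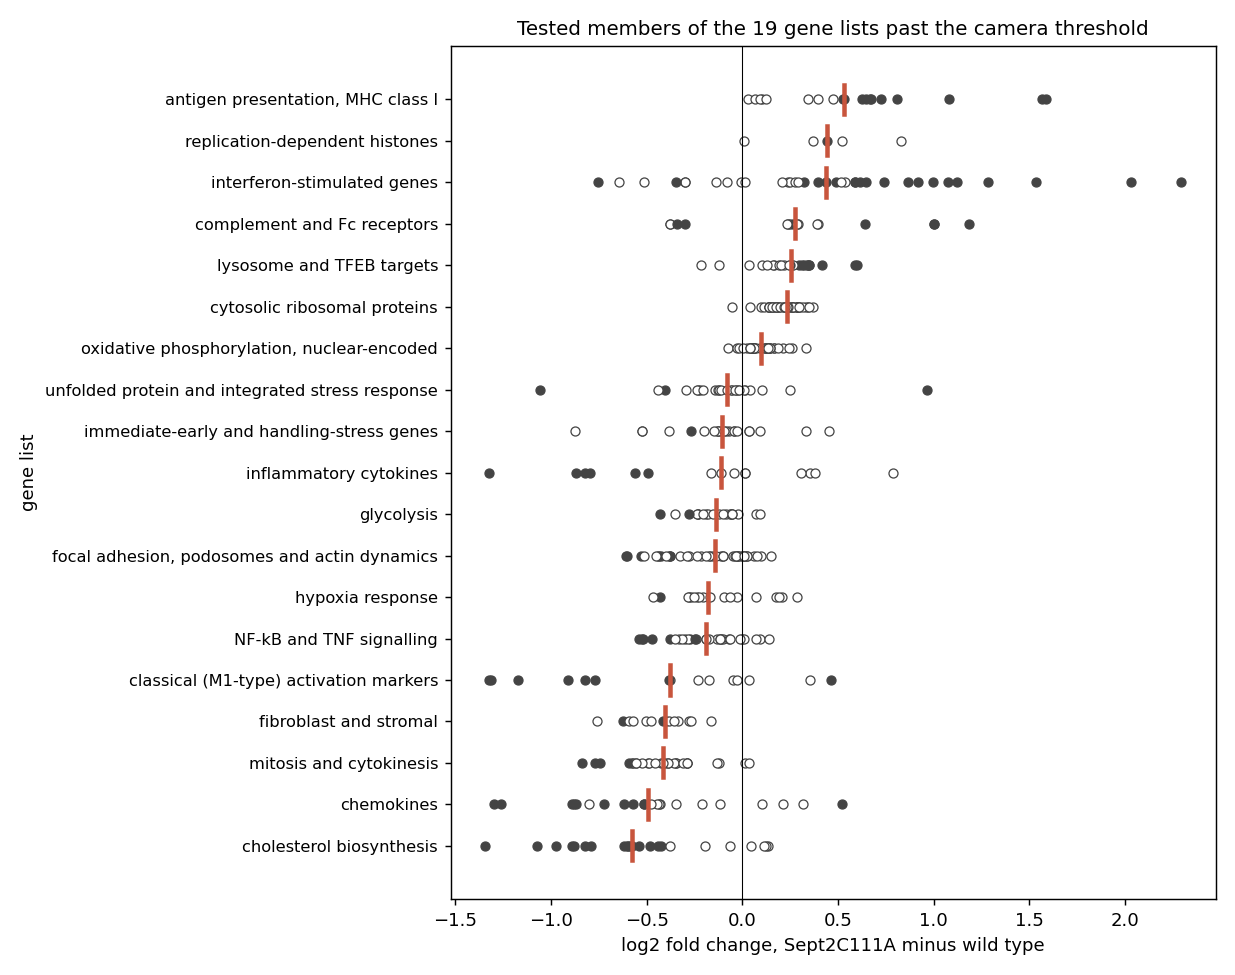
Log2 fold changes, Sept2C111A minus wild type, of the tested members of the 19 gene lists past the camera threshold at a preset correlation. Filled circles are genes called by edgeR at an adjusted p under 0.05, open circles are other members, and red bars are list medians, from -0.58 for cholesterol biosynthesis to 0.53 for class I antigen presentation.

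In the lists on cell migration, the axis of the exchange factor TIAM1, the GTPase RAC1 and the WAVE complex had 0 of 24 genes called by edgeR, 4 at an unadjusted p under 0.05, 1 called by DESeq2 and 1 by limma voom. The 0 depended on single libraries, since edgeR called 4 of the 24 lower without Sept2C111A library 4 and 1 without Sept2C111A library 1. These counts do not set the list apart. Without Sept2C111A library 4 edgeR called 2077 of 12583 tested genes, a share close to that of the list. In the main fit 3092 of all 12462 tested genes had an unadjusted p under 0.05. Arhgdia, its most abundant gene, measured 1512 ± 78.0 and 1535 ± 209 CPM. Rac1 measured 459 ± 15.5 and 459 ± 19.1 CPM, and Tiam1 had a log2 fold change of -0.40 (adjusted p 0.43), both chosen after their values were seen. The list was not called (camera adjusted p = 0.14, and 0.46 with an estimated correlation). Of 42 genes of focal adhesion, podosomes and actin dynamics, 9 fell and 0 rose, and 18 fell when adjusted over the list alone. Parvg, a parvin at integrin adhesions, fell from 25.0 ± 2.26 to 18.4 ± 1.03 CPM, and Fscn1, an actin-bundling protein gene, from 172 ± 13.6 to 127 ± 12.8 CPM, the latter call being lost without wild-type library 1, 3 or 4 or Sept2C111A library 2 (adjusted p 0.054 to 0.071). The list's median log2 fold change was -0.14 (camera adjusted p = 3.07e-05, and adjusted p = 0.20 with an estimated correlation). The falls numbered 1 without wild-type library 1 or 3, 2 without wild-type library 4, 3 without Sept2C111A library 2, and 4 without Sept2C111A libraries 2 and 3 together. The smooth muscle and fibroblast genes Tagln, Myl9, Tpm1 and Tpm2, named after their values were seen, were 4 of the 9.

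The list of fibroblast and stromal markers was called lower by camera at the preset correlation (median log2 fold change -0.41, adjusted p = 9.06e-06). That call was lost, at adjusted p = 0.44 with an estimated correlation. Of 14 genes, 3 fell and 11 did not pass, all 14 had a negative log2 fold change, and 10 fell when adjusted over the list alone. Acta2 went from 1016 ± 121 to 659 ± 112 CPM and Col1a1, the collagen gene, from 2056 ± 257 to 1545 ± 168 CPM, while Postn had a log2 fold change of -0.40 (SE 0.081). Each of these 3 calls was lost without wild-type library 1 or 3, and those of Postn and Col1a1 also without wild-type library 4 or Sept2C111A library 2, and of Col1a1 without Sept2C111A library 3 (adjusted p 0.056 to 0.15). The falls numbered 0 without wild-type library 1 or 3, 1 without wild-type library 4 or Sept2C111A library 2, 2 without Sept2C111A library 3, 6 without Sept2C111A library 1 and 10 without Sept2C111A library 4. In the fit without Sept2C111A libraries 2 and 3, 2 of the 14 fell. The list's mean log2 CPM was 5.52 and 5.54 in Sept2C111A libraries 2 and 3, 6.04 and 6.05 in libraries 1 and 4, and 6.13 to 6.39 in the wild-type libraries.

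Integrin and adhesion genes had Itga5 lower, from 414 ± 9.64 to 305 ± 19.7 CPM, Icam1 lower, from 936 ± 28.8 to 738 ± 88.5 CPM, and Pecam1 higher, from 2.92 ± 0.0968 to 4.02 ± 0.216 CPM, of 22 tested. Icam1 lost its call without any single wild-type library or Sept2C111A library 1 or 3, and Pecam1 without any single library but Sept2C111A library 4 (adjusted p 0.057 to 0.14). Without Sept2C111A library 4, 6 of the 22 fell. Adjusted over the list alone 2 rose and 4 fell (camera adjusted p = 0.071, and 0.46 with an estimated correlation). Among 25 matrix proteases and inhibitors, 4 rose and 1 fell, and 5 rose and 11 fell adjusted over the list alone. The rises numbered 2 without any single wild-type library or Sept2C111A library 2, and the falls 5 without Sept2C111A library 1 and 8 without Sept2C111A library 4. Ctsb and Ctsl, named after their values were seen, rose, and both calls were lost without any single wild-type library or Sept2C111A library 2. Adamts4 fell, its call lost without wild-type library 1 or 3 or Sept2C111A library 2 (adjusted p 0.055 to 0.062). The lysosomal protease gene Ctss rose from 900 ± 38.7 to 1313 ± 69.1 CPM, and Mmp27 had a log2 fold change of 0.58 (list camera adjusted p = 0.13, and 0.69 with an estimated correlation). Of 20 chemoattractant receptor genes, 3 rose and 2 fell (2 rose and 0 fell without any single wild-type library or Sept2C111A library 2, 3 rose and 1 fell without Sept2C111A library 1), and adjusted over the list alone 3 rose and 3 fell. C3ar1 rose and C5ar1 and Fpr2 fell, the call of C5ar1 being lost without any single wild-type library or Sept2C111A library 2 (adjusted p 0.061 to 0.098). Cxcr4, the receptor of CXCL12, rose from 34.5 ± 3.98 to 80.8 ± 9.29 CPM (list camera adjusted p = 0.62, and 0.77 with an estimated correlation).

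Of 24 lysosomal genes, 9 were called higher, 0 lower, and 16 higher and 1 lower when adjusted over the list alone. Gla, the alpha-galactosidase, went from 69.1 ± 1.19 to 104 ± 7.77 CPM and Npc2, a sterol carrier of the lysosome, from 833 ± 31.2 to 1261 ± 188 CPM (list median 0.26, camera adjusted p = 1.66e-07, and adjusted p = 0.22 with an estimated correlation). The 9 rises became 2 without wild-type library 1, 3 or 4 or with the replicate block, 3 without wild-type library 2 or Sept2C111A library 2, 7 without Sept2C111A libraries 2 and 3, and 14, with 1 fall, without Sept2C111A library 4. Of 29 mitosis genes, 4 fell and 25 did not pass (median log2 fold change -0.41, camera adjusted p = 4.18e-09, and adjusted p = 0.35 with an estimated correlation). The 4 were Cenpf, Prc1, Ube2c and the proliferation marker Mki67 (48.4 ± 1.46 to 28.9 ± 3.64 CPM), and 6 fell adjusted over the list alone. Cenpf was named after its values were seen. Prc1 and Ube2c lost their calls without any single wild-type library or Sept2C111A library 2 or 3 (adjusted p 0.053 to 0.12). Only 1 mitosis gene fell in each of these 6 fits and without Sept2C111A libraries 2 and 3, and 12 fell without Sept2C111A library 1. The mean log2 CPM of mitosis genes was 1.44 and 1.48 in Sept2C111A libraries 2 and 3, 1.95 and 1.70 in libraries 1 and 4, and 2.03 to 2.12 in the wild-type libraries. Stromal markers were likewise lowest in libraries 2 and 3, at 5.52 and 5.54. Of 25 S phase genes only Uhrf1 fell, also adjusted over the list alone, with its call lost without wild-type library 1, 2 or 3 or Sept2C111A library 2 (adjusted p 0.054 to 0.086) and 2 falls without Sept2C111A library 1, and the list was not called (camera adjusted p = 0.45, and 0.78 with an estimated correlation).

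In glycolysis, 2 of 20 genes fell (3 adjusted over the list alone), the lactate transporter gene Slc16a3 and the glucose transporter gene Slc2a1, the latter from 347 ± 22.9 to 257 ± 20.1 CPM (list median -0.14, camera adjusted p = 0.0016, and adjusted p = 0.46 with an estimated correlation). In the hypoxia list, which shares Slc2a1, that gene and Ero1a fell, of 19, and 1 rose and 9 fell adjusted over the list alone (camera adjusted p = 0.026, and adjusted p = 0.54 with an estimated correlation). The hypoxia call was lost at 0.12 without Sept2C111A library 3 and at 0.35 without Sept2C111A libraries 2 and 3, and 7 of its genes fell without Sept2C111A library 4. The list of unfolded protein and integrated stress response genes had 1 of 25 higher and 2 lower, and 1 higher and 6 lower adjusted over the list alone. Ddit3 rose from 22.2 ± 1.85 to 43.4 ± 11.2 CPM and the cystine transporter gene Slc7a11 fell from 48.3 ± 9.42 to 23.2 ± 6.74 CPM (camera adjusted p = 0.036 for a fall of the list, and adjusted p = 0.35 with an estimated correlation). The third called gene, Phgdh, fell, with its call lost without wild-type library 1, 3 or 4 or Sept2C111A library 2 (adjusted p 0.11 to 0.14), as were those of Slc16a3 and Ero1a without any single wild-type library or Sept2C111A library 2 (adjusted p 0.074 to 0.15). The call of the stress response list was lost without wild-type library 3 or 4 or Sept2C111A library 1 or 4 (adjusted p 0.054 to 0.16), and 4 of its genes fell without Sept2C111A library 1 or 4. Of 22 immediate-early and handling-stress genes 1 fell, Hsph1, at a log2 fold change of -0.27, and 3 adjusted over the list alone. That list was called lower (camera adjusted p = 0.031, and adjusted p = 0.35 with an estimated correlation), and the call was lost without wild-type library 3 or Sept2C111A library 3 or 4 (adjusted p 0.056 to 0.074) and with length and GC trends removed (0.059), and 2 and 3 of its genes fell without Sept2C111A library 1 and 4. Without any single wild-type library or Sept2C111A library 1 or 2, Hsph1 itself was not called (adjusted p 0.050 to 0.15).

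Camera also called the ribosomal protein, oxidative phosphorylation and histone lists higher at the preset correlation, all 3 lost, at adjusted p = 0.61, 0.74 and 0.22 with an estimated correlation. Of 43 ribosomal protein genes edgeR called 0, with 12 at an unadjusted p under 0.05, 2 called by DESeq2 and 0 by limma voom, but without Sept2C111A library 4 edgeR called 23 of them higher. Their median log2 fold change was 0.23 (camera adjusted p = 5.17e-06), and without Sept2C111A libraries 2 and 3 it was 0.02 and not called (adjusted p = 0.64). Of 34 oxidative phosphorylation genes edgeR called 0, with 2 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma voom, and without Sept2C111A library 4 edgeR called 3 higher. Their median was 0.10 (camera adjusted p = 0.036). The call was lost without wild-type library 2 or Sept2C111A library 2 or 3 (adjusted p 0.056 to 0.60), with a stricter filter (0.054) and with length and GC trends removed (0.32), and without Sept2C111A libraries 2 and 3 together the median reversed to -0.02. Of 5 histone genes 1 rose, H1f2, from 44.8 ± 3.76 to 60.7 ± 4.98 CPM, and 4 adjusted over the list alone (list median 0.44, camera adjusted p = 0.015). The histone call was lost with length and GC trends removed (adjusted p = 0.055), the median was 0.19 without Sept2C111A libraries 2 and 3, and 2 and 3 genes rose without Sept2C111A library 1 and 4. Libraries were selected on poly(A) tails, which most replication-dependent histone mRNAs lack.

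The other pathway lists were not called by camera. Of those that follow, fry called the inflammasome list higher (adjusted p = 0.032) and the oxidative stress list lower (adjusted p = 0.038). In the NLRP3 inflammasome list, Nlrp3 fell from 316 ± 14.2 to 196 ± 29.5 CPM and Nlrp1b rose, of 17 tested (camera adjusted p = 0.13, and 0.35 with an estimated correlation). Nlrp1b had a log2 fold change of 0.43, lost without any single wild-type library or Sept2C111A library 2 or 3 (adjusted p 0.053 to 0.099). Of 15 markers of alternative activation, Clec7a and Folr2 rose and Egr2 and Ccl22 fell, the log2 fold changes of the first pair being 0.54 and 0.43 (camera adjusted p = 0.44, and 0.66 with an estimated correlation). Of 13 genes of nitric oxide synthesis and denitrosylation, Txnrd1, the cytosolic thioredoxin reductase, fell from 846 ± 40.2 to 628 ± 50.2 CPM and Slc7a2, an arginine transporter gene, had a log2 fold change of -0.77 (camera adjusted p = 0.88, and 0.94 with an estimated correlation). That list's median of 0.02 and mean of -0.04 differed in sign. Txnrd1 and Slc7a11 were the 2 of 19 oxidative stress genes that fell (camera adjusted p = 0.083, and 0.46 with an estimated correlation). Of 16 scavenger receptor and efferocytosis genes, Marco fell and Gas6 had a log2 fold change of 0.35 (camera adjusted p = 0.71, and 0.77 with an estimated correlation); the median of 0.03 and mean of -0.06 differed in sign. Adjusted over the list alone, the rises and falls numbered 2 and 2 for the inflammasome, 2 and 4 for alternative activation, 2 and 2 for nitric oxide, 0 and 6 for oxidative stress, and 5 and 1 for scavenger receptors. Leaving out libraries ended calls of Egr2 (wild-type 1 or 3 or Sept2C111A 2), Ccl22 (wild-type 2, 3 or 4 or Sept2C111A 3), Slc7a2 (any wild-type or Sept2C111A 2) and Gas6 (wild-type 1 or 3), with adjusted p between 0.051 and 0.11. Without Sept2C111A library 4, the rises and falls numbered 4 and 2 for the inflammasome, 2 and 5 for alternative activation, 1 and 2 for nitric oxide, 2 and 6 for oxidative stress, and 3 and 1 for scavenger receptors.

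Among lists of cell identity, macrophage markers had 2 of 17 higher, Fcgr1 and Apoe, with 4 higher and 0 lower adjusted over the list alone, and 1 higher without any single wild-type library, 4 higher and 1 lower without Sept2C111A library 4 (camera adjusted p = 0.20, and 0.45 with an estimated correlation). Of the T and NK cell markers tested, Cd4 rose from 14.5 ± 0.563 to 21.1 ± 2.12 CPM and Il7r from 27.7 ± 1.73 to 43.3 ± 8.52 CPM, also adjusted over the list alone. Camera did not call the list of 5 (adjusted p = 0.24, and 0.46 with an estimated correlation). Fry called the macrophage list (adjusted p = 0.021) and the T and NK cell list (adjusted p = 0.048) higher. Of 7 dendritic cell markers Fscn1 and Ccl22 fell, and 1 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.45, and 0.69 with an estimated correlation); the median of 0.08 was positive and the test pointed down. For neutrophil, monocyte, osteoclast, endothelial, and erythroid and megakaryocyte markers edgeR called 0 genes of 7, 6, 7, 5 and 5, with 3, 4, 3, 1 and 1 at an unadjusted p under 0.05. DESeq2 called 1, 0, 1, 0 and 0 of them, and limma voom called 0 in each list. Without Sept2C111A library 4 edgeR called 2 neutrophil, 3 monocyte and 1 osteoclast marker, and without Sept2C111A library 1 it called 1 of each and 1 endothelial marker. Without wild-type library 2 or Sept2C111A library 3 it called 1 neutrophil marker. Camera gave these 5 lists adjusted p of 0.85, 0.35, 0.20, 0.73 and 0.99, and 0.86, 0.65, 0.53, 0.77 and 1.00 with an estimated correlation. Adjusted over the list alone, 1 neutrophil, 1 monocyte and 1 endothelial marker rose and 3 monocyte and 1 osteoclast marker fell. The median of the erythroid and megakaryocyte list, -0.01, and its mean, 0.06, differed in sign. Their most abundant members were Csf3r, at 137 ± 18.5 and 186 ± 27.1 CPM, Fn1, at 1593 ± 128 and 1100 ± 405 CPM, Mmp9, at 157 ± 20.9 and 107 ± 29.2 CPM, Eng, at 130 ± 5.53 and 143 ± 12.5 CPM, and Gp1ba, at 2.66 ± 0.438 and 2.91 ± 1.14 CPM. Mast cell and B cell lists had 1 tested gene each, Mcpt8 and Cd79b, neither called. Of 4 sex-linked transcripts edgeR called 0, with 1 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma voom (camera adjusted p = 0.35, and 0.68 with an estimated correlation), 1 rose adjusted over the list alone, and 1 was called without Sept2C111A library 4. Of 5 genes that vary between mouse strains, Wdfy1 rose from 10.2 ± 0.759 to 21.1 ± 0.967 CPM, and 1 rose and 2 fell adjusted over the list alone. Camera did not call this list (adjusted p = 0.85, and 0.86 with an estimated correlation), while fry called it higher (adjusted p = 0.021). The mean log2 CPM of that list was 3.22 to 3.37 in wild-type libraries 1 and 3 and Sept2C111A library 1 and 4.23 to 4.48 in the other 5. The split lay in Entpd4, chosen after its values were seen, at 0 CPM in those 3 libraries and 2.74 to 4.56 CPM in the others. Its close copy Entpd4b, with which it shares reads, measured 39.1 to 47.4 CPM in all 8. Wdfy1, Cyfip2, Mid1 and Nnt overlapped between these sets of libraries or followed the genotype. Wild-type libraries 1 and 3 also had the lowest mean log2 CPM of interferon-stimulated genes. Sept2C111A library 1, at 6.69, lay above Sept2C111A library 4, at 6.64, so the split did not order the Sept2C111A libraries. A link between Entpd4 and the interferon genes was not tested.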

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

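The comparisons of summed marker levels and with the median of all genes were chosen after the result was seen, and so were the fits that remove length and GC trends or take the stromal score as a covariate. Ifi213, an interferon-inducible gene, stood at 44.9 CPM in Sept2C111A library 2, and the other 3 Sept2C111A libraries lay between 29.4 and 31.8 CPM. It was the only one of 84 groups of 4 values in which the most distant library passed the criterion, where chance alone gives about 1 in 20. A share of 1 in 84 is below that, so the criterion does not set this value apart from chance. Ifi213 belongs to a family of close copies on chromosome 1, so its reads were shared out by the counting model.

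Interferon-stimulated genes had a median log2 fold change of 0.44 over 35 genes, 9 of them negative, and the list call was lost with an estimated correlation. Other scalings left this median at 0.438 or more and moved too little to test anything, but scaling shifts all genes of a library alike, and the list's median exceeded that of all tested genes by 0.43. Removing trends on transcript length and GC content left 1.02 of the median. For RNA of another cell type, the highest median among the types compared, that of 7 neutrophil markers, was 0.545 of the interferon median, between the bounds set in advance. The largest rise of summed markers among these types was 47.3 CPM against 1375 CPM for the interferon genes, a share of 0.0344. These values argue against scaling and against transcript length or GC content. They leave RNA of another cell type undecided, as the bound of 0.1 for the sums was chosen after the sums had been seen. Neutrophil and T and NK cell markers summed to only 152 and 43.9 CPM in wild-type libraries, so a small rise in CPM says little about them. The neutrophil sum of 152 CPM, and of 199 CPM in Sept2C111A libraries, was mostly Csf3r, at 137 and 186 CPM. Its rise of 47.3 CPM therefore rests on 1 gene. Monocyte markers, at 1750 CPM in wild-type libraries, fell to 1195 CPM, but most of both sums was Fn1, at 1593 and 1100 CPM. Fn1 overlapped between the groups and was not called (edgeR adjusted p 0.15), so these sums say little about monocytes. B cell and mast cell markers had 1 tested gene each. Dendritic cell markers were compared too, but osteoclast, erythroid and megakaryocyte, stromal and endothelial markers and types outside the lists were not. The genotype stays open as a hypothesis.

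Cholesterol biosynthesis genes and inflammatory genes had a lower mean log2 CPM in Sept2C111A libraries, where the stromal score was lower too. Fewer stromal cells would remove both differences once the stromal score enters as a covariate. The cholesterol difference in mean log2 CPM over 23 genes kept 0.865 of its size, from -0.52 (SE 0.055) to -0.45 (SE 0.082). The difference over 77 inflammatory genes kept 0.974, from -0.33 (SE 0.051) to -0.32 (SE 0.084). Over single genes the fit with the covariate called 94, of which 91 were among the 805, the score being lower in Sept2C111A libraries and sharing part of the genotype term. Both differences argue against stromal share, as this score measures it, as the whole cause, and a change in the macrophages that goes with the genotype stays open. The score did not overlap between the genotypes, at 6.13 to 6.39 in wild-type and 5.52 to 6.05 in Sept2C111A libraries. Its slope therefore rests largely on differences among Sept2C111A libraries, and a kept share cannot exclude a stromal part.

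Splits of these libraries set the number of called genes apart from that of other groupings, but not the number of called lists. Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many genes as the 805 of the real split, the real one itself, and the highest of the others gave 0. That is the smallest share that 35 splits allow, so chance is made less likely and not excluded. The splits also treat libraries as independent samples, which the labels do not say. For gene lists, 2 of the 35 splits gave as many as the 19 of the real split, itself included, and the highest of the others gave 20.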

How the results depend on the processing

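Fits on length and GC content, the stromal score and libraries 2 and 3 together were chosen after the data were seen. Called genes were 494 with the replicate block (242 higher, 252 lower), 1402 with DESeq2 (693, 709), 1343 with voom sample weights (665, 678) and 2043 with a surrogate variable (1032, 1011). They were 37 against a fold of 1.5 (29, 8), 220 at an adjusted p under 0.01 (136, 84) and 96 with an absolute log2 fold change of at least 1 (61, 35). Without Sept2C111A libraries 2 and 3 they were 492 (282, 210), with length and GC trends removed 1250 (707 higher), and with the stromal score as a covariate 94 (60, 34), of which 91 were among the 805; the score is lower in Sept2C111A libraries, so it shares part of the genotype term. Leaving out 1 library gave 266 to 2077 genes, 162 to 1094 higher and 104 to 983 lower. The cause of these moves was not tested, save that stricter thresholds lower a count by construction. None of the 805 changed sign in any of these fits. RLE size factors called 816, of which 802 were among the 805.

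The log2 fold change of Sept2 passed the threshold with DESeq2 (-0.26, adjusted p 0.020), voom sample weights (-0.26, 0.018), the surrogate variable (-0.33, 0.00059), length and GC trends removed (-0.33, 0.011) and without Sept2C111A libraries 2 and 3 (-0.37, 0.016); the cause was not tested. Leaving out 1 library gave -0.31 to -0.20. Lists called by camera numbered 16 to 20 in other fits and 21 by fry (15 shared), and 0 with an estimated correlation, where 6 had an unadjusted p under 0.05. The median of oxidative phosphorylation genes reversed to -0.024 without Sept2C111A libraries 2 and 3. Of 85 named genes past the threshold, 57 stayed past it in all 17 planned fits, 28 were lost on leaving out some library, 13 in another planned fit, and 0 reversed, while the stromal score as a covariate ended 50 of the 85 calls and leaving out Sept2C111A libraries 2 and 3 ended 20; of 19 lists, 14 stayed in 13 planned fits. The values gave no sign that replicate numbers pair the samples: the correlations of same-numbered libraries were 0.14, 0.096, -0.02 and -0.24, and 1 of 4 wild-type libraries correlated best with its own number. With 4 libraries per group this does not exclude shared mice, days or batches, which the labels do not give. Depth limits statements on genes below about 0.15 CPM.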

Other observations

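The count of called genes around Sept2 with Wdfy1 left out was chosen after the result was seen. Several genes outside the lists and the naming rule were among those with the smallest adjusted p, and they were chosen after their values were seen. Il18bp, the binding protein that neutralizes interleukin 18, had a log2 fold change of 1.11 (SE 0.095), higher in 4 of 4 Sept2C111A libraries. Lgals3bp, a secreted galectin ligand, rose from 569 ± 26.7 to 1176 ± 152 CPM and Lgals9, galectin 9, from 113 ± 4.69 to 200 ± 24.3 CPM. Cd22, a sialic acid-binding receptor known from B cells, rose from 12.9 ± 0.611 to 23.2 ± 1.82 CPM. Gpr84, a receptor for medium-chain fatty acids, fell from 235 ± 8.85 to 123 ± 17.4 CPM, and Slc13a3, a dicarboxylate transporter gene, from 32.1 ± 2.49 to 15.4 ± 1.94 CPM. Jdp2, a repressor of the AP-1 family, fell from 120 ± 4.74 to 60.1 ± 10.6 CPM. All 4 values of Camk2b were between 2.24 and 2.65 CPM in Sept2C111A libraries and at or under 0.477 CPM in wild-type libraries. Ifnb1, the interferon beta gene, had 1 read in wild-type library 2 and none in the other libraries, and a count of 0 allows up to 0.154 CPM in the library with the smallest total.

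Wdfy1 lies on chromosome 1, as does Sept2, and its level differs between laboratory strains, so a hypothesis is that a segment around Sept2 from another strain came with the allele. Of 145 tested genes within 20 Mb of Sept2, 11 were called, or 7.59%, against 6.43% of the 12281 elsewhere (one-sided Fisher exact p = 0.33). Wdfy1 itself is among the 11, and without it 10 of 144 were called, or 6.94% (one-sided Fisher exact p = 0.45). Both shares lie slightly above that elsewhere and within what chance gives, so the counts leave this possible segment undecided.

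Sept2C111A libraries spread more than wild-type libraries, with a biological coefficient of variation of 0.138 against 0.0604. The ratio of the coefficients was 2.28 before and 2.28 after every library was thinned to the smallest total. Thinning removed at most 8.19% of a library's reads, so the totals were close from the start. A ratio of 2.28 at equal totals argues against differences in total reads as its cause. Transcript length and GC content together explained 0.155 of the variance across 12242 genes of the deviation of Sept2C111A libraries 2 and 3 from 1 and 4. That is between the bounds set in advance, so a part of the spread may follow them. The labels give no batch, culture or mouse that could be set against the rest.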
